A study of Mus musculus with 4 samples.

How the data were processed

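RNA was extracted with Trizol from cerebral cortex of C57BL/6 mouse embryos at embryonic day 15, and libraries were made from 2 µg of total RNA with an Illumina TruSeq RNA kit and sequenced on a HiSeq instrument, per the labels' protocols. That kit does not mark the strand of origin, so reads of a gene and of an antisense partner cannot be told apart where their exons overlap. The labels put 2 samples in the conditional knockout group (Prdm16 cKO) and 2 in the control group of mice carrying the floxed Prdm16 alleles. They do not name the Cre line or the deleted exon. The word Blood stands in the title of 1 sample of each group without an explanation, and which columns these samples gave, if any, is not known. The series' design text speaks of triplicates and of telencephalic tissue, where the labels list 2 samples per group and cortex.

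The measurements came from 2 deposited tables, each setting a library of the knockout group beside the same library of the control group. The column names hold KO or WT, as do the titles of the samples with the cKO and floxed genotypes, and libraries were assigned to groups on this ground. The names do not show which sample each library was. The libraries are called cKO 1, cKO 2 and floxed, and the numbers are names only. The other sample labelled floxed was not analysed here. The control column held identical counts in both tables for every shared gene and was used once. Nothing in the sources used here says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

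The authors deposited raw counts per gene, with genes identified by Ensembl gene IDs and paired with symbols in the tables, per the file headers. Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 are named, with mm9 as the genome build, per the submitters' processing notes. The positions printed in the deposited tables are not those of mm9. Of 21767 genes in either table, 21707 had a gene of the same ID in GENCODE M21 (GRCm38), 21705 of these lay at an overlapping position and 19572 at the identical one. Coordinates are therefore given as in the tables and called GRCm38. The counting options, including the treatment of reads with several matches, are not given in the sources used here. From the values, a gene was listed in a table when both libraries had at least 1 read, or when a library had 0 and the other at least 5. Beside the counts the authors gave normalized values, which from the values were counts scaled to the library total (CPM) with a count of 0 replaced by 0.5. The authors' fold was the ratio of these CPM values, and the authors' log2 fold was its logarithm. The authors' p-values and adjusted p-values compare 1 library with 1 library, and the test behind them is not given in the sources used here. Genes marked significant in the authors' deposited tables had adjusted p-values of at most 0.0499 in both tables and absolute log2 folds of at least 1.

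The tables listed 21102 and 20633 genes. The 19968 genes in both were used, which left out 1134 genes listed with cKO 1 alone and 665 listed with cKO 2 alone. Totals over the tables were 19514882 counts for cKO 1, 18579178 for cKO 2 and 17838603 for floxed. The 10 genes with the most counts took 5.58%, 5.44% and 5.21% of them. At these depths the upper limit that a count of 0 allows (3 counts) was 0.152, 0.165 and 0.167 CPM. Ratios of counts between 2 libraries are given with 95% exact (Clopper-Pearson) intervals from the conditional binomial distribution. The reads carry no molecular identifiers, so intervals and limits cover counting error only.

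The deposited counts were tested with edgeR 4.0.16 in R 4.3.3: the default expression filter with a minimum count of 10 left 16725 genes, library sizes were scaled by TMM (factors 1.01, 0.978 and 1.01), and the quasi-likelihood test compared the 2 cKO libraries with the floxed library, with Benjamini-Hochberg adjustment over all genes. This leaves 1 residual degree of freedom. The spread was estimated from the cKO libraries alone, and the lone floxed library was assumed to vary like them. The common biological coefficient of variation was 0.218 and the prior degrees of freedom were 3.71. The standard error (SE) of a fitted log2 fold was its size divided by the square root of the F statistic. The fold of each cKO library against floxed was taken on log2 CPM with TMM and a prior count of 2, and carries no test.

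Before the data were examined, 25 gene lists, the rule for named genes and the alternatives were fixed, apart from those said to be chosen later. Lists with at least 5 tested members (24 of them) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry, whose directional test is meant unless the mixed one is named. Beside each list stands its median fold per library. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, was also taken and is not given below. The named genes are Prdm16, the 12 genes per direction with the largest value of the smaller of their absolute log2 folds in the 2 cKO libraries, moving the same way in both and with at least 5 CPM in the higher group, and up to 4 members of each list by the same measure. Of the genes reached by this rule, 3 higher and 4 lower ones without a proper name were passed over. Any gene named outside the rule was chosen after its values were seen, also where this is not said beside it.

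Both folds share the floxed library, so their agreement was set beside 100 simulated sets of unchanged libraries sharing a control, made with the fitted spread and with counting error only. Annotation terms attached to genes in the tables (10 to 500 genes in a background of 15146 annotated tested genes, 2901 terms) were tested with a one-sided Fisher exact test. On data simulated for this comparison over 16725 genes, with 50 genes at each fold and a spread that varied by gene, the edgeR test recovered 0 of 50 genes at 2-fold, 29 of 50 at 4-fold, 38 of 50 at 8-fold and 43 of 50 at 16-fold, with 13 unchanged genes called. With 1 spread per expression level it recovered 17, 45, 49 and 50 of 50, with 5 unchanged genes called. This setting replaced an earlier simulation with a smaller spread, whose results are not given. The changed genes were drawn from those with a mean level above 5 CPM, and both spreads built on the one fitted to these libraries. Alternatives covered the normalization, the expression filter, the tool (DESeq2 1.42.0 and limma-voom), the prior count, the fold threshold, the level minimum, the term size and each cKO library left out. Exon overlaps between genes were taken from GENCODE M21. Figures were drawn with matplotlib in Python.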

Results

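Gene expression was measured by RNA sequencing in the forebrain cortex of mouse embryos at embryonic day 15, in embryos with a conditional deletion of Prdm16 (cKO) and in controls carrying the floxed alleles. Prdm16 encodes a zinc-finger transcriptional regulator with a PR domain that is expressed in cortical radial glia. The study addressed how Prdm16 acts on signals between neural cells and blood vessels in the developing brain. The tables held 2 libraries labelled cKO, with 19514882 and 18579178 counts, and 1 control library, called floxed here, with 17838603 counts. Errors can therefore be given for the cKO group only, as the SD of 2 libraries, and every level quoted for the floxed group is that of 1 library.

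Prdm16 itself was not uniformly lower in the libraries labelled cKO. The gene (ENSMUSG00000039410, GRCm38 chromosome 4, 154316125 to 154636873, minus strand) had 676 counts in cKO 1, 447 in cKO 2 and 538 in floxed, or 34.2, 24.6 and 29.9 CPM. The cKO mean was 29.4 ± 6.78 CPM (SD, n = 2), and the fitted log2 fold was -0.03 (SE 0.25, edgeR adjusted p = 1). Against floxed, the log2 fold was 0.19 in cKO 1, with a count ratio between 1.02 and 1.28 (exact 95% interval), and -0.28 in cKO 2, with a ratio between 0.723 and 0.933. In the authors' deposited tables the log2 folds were 0.20 (adjusted p = 0.0514) and -0.33 (adjusted p = 0.00165), and neither was marked significant. The level in cKO 1 runs against its label, although a count over all exons need not drop when part of a gene is deleted. The labels do not give the deleted exon, so the total checks them only in part, and directions below refer to libraries labelled cKO.

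Ptx3, which encodes a secreted pentraxin of innate immunity, had the largest shared fold among higher genes of at least 5 CPM, taking the smaller of the folds in the libraries labelled cKO. Its level was 109 ± 6.12 CPM (SD, n = 2) in cKO and 16.9 CPM in floxed, a log2 fold of 2.73 in cKO 1 and 2.62 in cKO 2. Fgf15, a fibroblast growth factor, was 5.77-fold higher in cKO 1 and 5.22-fold in cKO 2, and Moxd1, a monooxygenase related to dopamine beta-hydroxylase, 9.61-fold and 5.03-fold. Fgfbp3, a secreted FGF-binding protein, went from 32.7 CPM in floxed to 72.4 ± 9.07 CPM (SD, n = 2) in cKO. Kremen1, a Dickkopf receptor that restrains Wnt signalling, went from 20.7 to 44.3 ± 1.83 CPM, and Gabra2, a GABA-A receptor subunit, from 38.6 to 99.4 ± 28.9 CPM. The axon guidance receptor Robo3 (log2 folds 1.57 and 1.24), the metalloprotease Adamts20 (1.02 and 1.04) and the cadherin Cdh20 (1.19 and 1.27) were also higher in both. Scrg1 (1.23 and 1.48), Veph1 (1.45 and 1.11) and Pdlim3 (0.97 and 1.19) complete the 12 named genes of this direction.

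Among genes lower in both libraries, the calpain gene Capn11 had 5.95 CPM in floxed and 0.315 ± 0.0558 CPM (SD, n = 2) in cKO, on 7 and 5 counts against 107. The secreted calcium-binding protein Smoc1 had 36.0 CPM in floxed and 13.7 ± 3.99 CPM in cKO, with log2 folds of -1.12 and -1.71. The collagen gene Col22a1 (-1.21 and -1.98), the extracellular matrix gene Vit (-1.08 and -1.46) and the iron-reducing enzyme gene Cybrd1 (-1.40 and -1.93) followed. The GABA transporter gene Slc6a11 had 30.3 CPM in floxed and 15.1 ± 0.742 CPM in cKO, and the POU-domain factor Pou3f4 had 15.1 CPM in floxed and 6.07 ± 2.43 CPM in cKO. Siah3 (-1.15 and -1.12), Adcy2 (-0.82 and -0.79), Xkr7 (-0.78 and -1.09), Epha10 (-1.22 and -0.75) and the pseudogene Tmem181b-ps (-1.69 and -0.85) make up the rest. Tmem181b-ps can share reads with its parent family, and its value is uncertain.

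**Figure D1:**
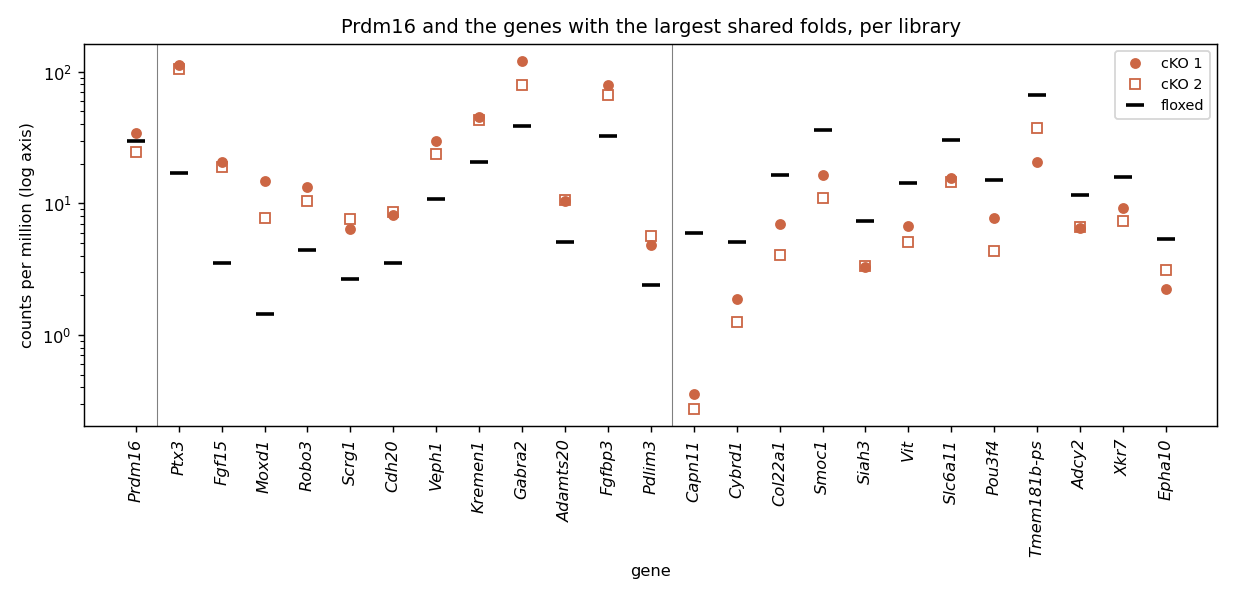
Normalised counts (CPM) on a log axis for Prdm16 (left), the 12 named genes higher (middle) and the 12 lower (right) in both libraries labelled cKO. Each circle or square is a cKO library and each bar the floxed library. Ptx3 sits at 113 and 104 CPM against 16.9, while Prdm16 has the floxed value between its cKO values.

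No gene passed the adjusted threshold. The edgeR quasi-likelihood test called 0 of 16725 genes at a Benjamini-Hochberg adjusted p under 0.05, with 217 genes at an unadjusted p under 0.05 where 836 would be expected by chance, and limma-voom also called 0. The smallest adjusted p was 0.346, for Ptx3 (fitted log2 fold 2.68, SE 0.16), and the other 23 named genes had an adjusted p of 1. DESeq2 called 5 genes, all higher in both libraries: Ptx3 (adjusted p = 1.77e-26), Fgf15 (0.000173), Gabra2 (0.0033), Fgfbp3 (0.0194) and Moxd1 (0.0194). With total counts in place of TMM, edgeR called Ptx3 alone (adjusted p = 0.00853). On simulated data, with changed genes above 5 CPM, the edgeR test found 0 of 50 genes at 2-fold when the spread varied by gene. It found 17 of 50 when the spread did not vary, so most 2-fold differences were not detectable by this test. Both settings built on the fitted spread, which gave simulated log2 folds of cKO 1 a wider SD than observed (0.583 against 0.404). Fewer small unadjusted p-values than expected also mark the test as cautious here. Its 0 calls therefore do not show that little changed.

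Ptx3 (chromosome 3, 66219910 to 66225805, plus strand) lies within the span of Veph1 (66053558 to 66296837, minus strand), and the exons of these genes do not overlap in GENCODE M21. Fgf15 (chromosome 7, 144896531 to 144900953) shares 24.9% of its exon bases with the antisense gene Gm26793, which was also higher in both libraries (log2 folds 1.60 and 1.33), so their reads cannot be separated there.

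Each library labelled cKO was next set against floxed alone, as in the deposited tables. In cKO 1, 331 genes were higher and 258 lower by over 2-fold, and in cKO 2 the numbers were 270 and 1079. Genes at 10 CPM or more in the highest of the 3 libraries gave 21 and 8 in cKO 1 and 15 and 179 in cKO 2, so most abundant genes past 2-fold were lower genes of cKO 2. In both libraries 101 genes were higher and 101 lower, while 37 were higher in cKO 1 and lower in cKO 2 and 3 the other way. Independent lists would share 5.34 higher and 16.6 lower genes. Simulated unchanged libraries sharing a control shared 334 and 185 with the fitted spread, and 34.6 and 8.69 with counting error alone. For the 37 and 3 genes of opposite direction, the simulated numbers were 7.58 and 9.66 with the fitted spread. With counting error alone they were 0.11 and 0.18. The fitted spread comes from the difference between the cKO libraries. It gave the log2 folds of cKO 1 a wider SD than observed (0.583 against 0.404), and those of cKO 2 a similar one (0.587 against 0.59). Observed counts below the simulated ones therefore do not show less agreement than unchanged libraries would have.

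Of the abundant genes, 10 were higher and 3 lower in both libraries, against 25.2 and 8.99 in simulated unchanged libraries with the fitted spread and 0 and 0 with counting error alone. Across all tested genes, which are not independent replicates, the log2 folds of the cKO libraries correlated with r = 0.20 and a covariance of 0.0475. The simulated values were 0.50 and 0.172 with the fitted spread and 0.51 and 0.0329 with counting error alone. Among the abundant genes r was 0.01 and the covariance 0.00107. There the simulated values were 0.50 and 0.0669 with the fitted spread and 0.51 and 0.00362 with counting error alone. The abundant genes as a set therefore showed almost no correlation between the cKO libraries. The control cannot be split, so part or all of the agreement may come from the shared floxed library. In the authors' deposited tables, a total of 495 genes were marked significant for cKO 1 (307 higher, 188 lower) and 1387 for cKO 2 (228 and 1159). Of these, 58 were higher in both and 74 lower in both, where independent lists would share 2.72 and 10.9, and 21 were higher in cKO 1 and lower in cKO 2. These comparisons share the floxed library too, so independent lists are not their no-change level, and no other level was simulated for them. The 58 include Ptx3, Fgf15, Moxd1 and Kremen1, and the 74 include Capn11, Smoc1 and Vit.

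**Figure D2:**
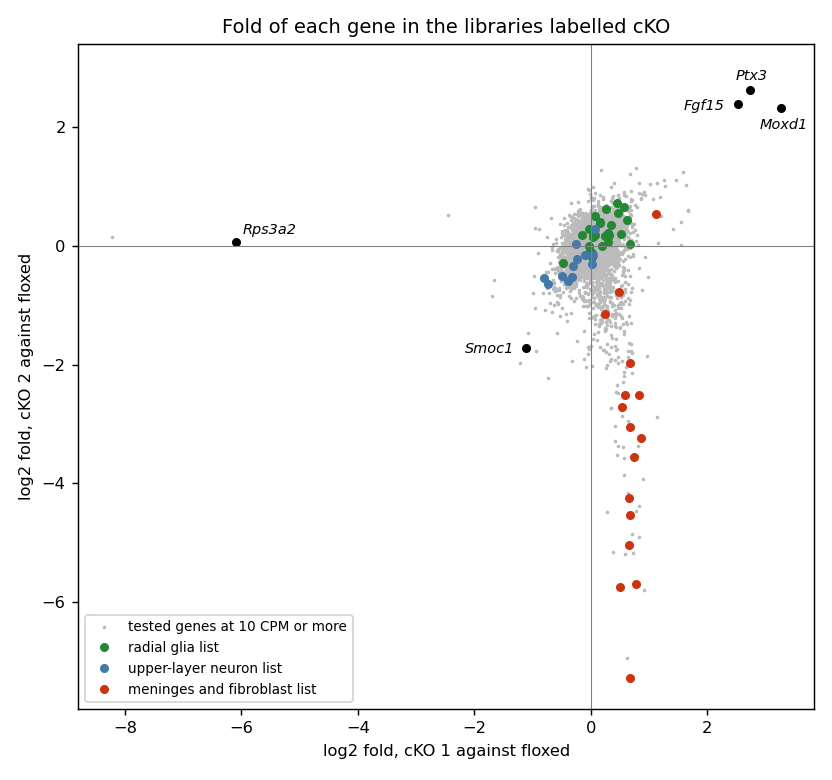
Log2 fold of each gene in cKO 1 (horizontal) and cKO 2 (vertical) against the floxed library, for tested genes at 10 CPM or more in their highest library. Each point is a gene, with members of 3 lists coloured and a few genes labelled in black. Ptx3, Fgf15 and Moxd1 lie at the upper right, and the meninges genes spread downwards, with Col1a1 at a log2 fold of -5.03 in cKO 2.

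Markers of upper-layer cortical neurons were lower in both libraries labelled cKO. Of 13 tested members 9 were lower in both beyond counting error and 1, Mdga1, was higher, with a median log2 fold of -0.30 in cKO 1 and -0.34 in cKO 2. The transcription factor gene Cux2 had 160 CPM in floxed and 91.4 and 110 CPM in the cKO libraries, the netrin receptor gene Unc5d 47.1 against 28.4 and 30.2 CPM, and the POU factor gene Pou3f1 59.9 against 42.5 and 42.1 CPM. Inhba, which encodes an activin subunit, had 5.90 CPM against 3.59 and 2.64. The list was called by camera (adjusted p = 2.93e-10), but not with an estimated correlation (adjusted p = 0.855). Over all genes 0 members passed edgeR's test, and 3 did so adjusted over the list alone (smallest adjusted p = 0.0496).

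Radial glia genes, which mark the neural stem cells of the ventricular zone, were mostly higher: 20 were higher in both libraries, 3 lower in both and 5 split. Pax6 (-0.04 and -0.01) and Notch1 (-0.02 and -0.08) stayed within counting error. Gli3 (0.02 and -0.19) and Sox1 (0.03 and -0.12) were split. These members were chosen after their values were seen. Of 28 members 12 were higher in both beyond counting error and 1, Mfge8, was lower, and the medians were 0.17 and 0.19. The intermediate filament gene Vim had 568 CPM in floxed and 847 and 894 CPM in cKO, the lipid-binding protein gene Fabp7 473 against 653 and 694 CPM, the transcription factor gene Sox9 44.1 against 68.0 and 59.6 CPM, and Hopx 8.96 against 12.2 and 14.9 CPM. Hopx shares 27.2% of its exon bases with an antisense gene. Camera called the list (adjusted p = 3.03e-08), and with an estimated correlation it was not called (adjusted p = 0.855). No member passed edgeR's test over all genes, and 0 passed adjusted over the list alone.

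Markers of deep-layer neurons were higher in 9 of 15 members in both libraries, 7 of them beyond counting error, with medians of 0.25 and 0.11. Another 5 went in opposite directions, among them Foxp1 (0.07 and -0.70) and Foxp2 (0.14 and -0.64), which were lower in cKO 2 beyond counting error and were chosen after their values were seen. Fezf2, a determinant of subcerebral projection neurons, had 213 CPM in floxed and 253 and 299 CPM in cKO, Tle4 59.1 against 71.9 and 71.9 CPM, Zfpm2 17.2 against 20.5 and 22.1 CPM, and Nfib 954 against 1172 and 1132 CPM. Camera called this list too (adjusted p = 0.0049), and with an estimated correlation it was not called (adjusted p = 0.855). Pan-neuronal genes had medians of -0.07 and 0.02 and cell cycle genes 0.09 and 0.03, and neither list was called (camera adjusted p = 0.863 and 0.369). Beyond counting error, 3 of 24 pan-neuronal members were higher in both libraries and 7 lower, and 4 and 1 of 30 cell cycle members. The axon guidance list, also not called, had 6 and 5 of 28. Such counts therefore also arise in lists that were not called. Mapt, a microtubule-binding protein of axons, was lower in both (-0.29 and -0.22), as were Scg2 (-0.42 and -0.19) and Nefm (-0.25 and -0.19), while Neurod1 was higher (0.38 and 0.40). The medians of the intermediate progenitor list were -0.13 and 0.17 (adjusted p = 0.653). Within it Insm1 had 198 CPM in floxed and 143 and 144 CPM in cKO, Eomes had log2 folds of -0.29 and -0.22, Rgs16 -0.50 and -0.25, and Nhlh1 0.21 and 0.65.

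Genes of meninges and fibroblasts separated the libraries labelled cKO. All 19 tested members were higher than floxed in cKO 1, with a median of 0.65, and 18 of 19 were lower in cKO 2, with a median of -2.72. Dcn, which encodes the proteoglycan decorin, had 33.6 CPM in floxed, 55.9 in cKO 1 and 2.75 in cKO 2, and Lum had 14.1, 24.2 and 0.165 CPM. Ogn had 10.3, 18.7 and 0.991 CPM and Ptgds, the prostaglandin D2 synthase gene, 23.4, 41.8 and 4.02 CPM. In the pericyte and smooth muscle list (medians 0.19 and -1.03), 14 of 15 members went in opposite directions, with Acta2 at 9.63, 12.5 and 0.165 CPM. The choroid plexus and hem list (0.21 and -1.34) was mixed: of 19 members 9 went in opposite directions, such as Enpp2 at 32.3, 41.2 and 8.53 CPM, 6 were lower in both and 4 higher in both, among them Rspo3 (0.38 and 0.42). Camera called the meninges list (adjusted p = 0.0203) and the pericyte list (0.0362) as lower on average but not the choroid plexus list (0.0851), and none was called with an estimated correlation (adjusted p = 0.855 for each). The estimated correlation was 1 for the meninges list and 0.733 for the pericyte list, far above the preset 0.01 behind the calls. Without cKO 2 the medians of the called lists turn to those of cKO 1, above 0.

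Endothelial genes, the markers of the vessels that the study was concerned with, went in opposite directions in the libraries labelled cKO, in the same order as the meninges list. In cKO 1, 29 of 32 were higher, 15 beyond counting error, with a median of 0.26, and in cKO 2, 30 of 32 were lower, 26 beyond counting error, with a median of -0.74. Cdh5, the endothelial cadherin gene, had 43.9 CPM in floxed, 68.9 in cKO 1 and 22.3 in cKO 2, and the angiopoietin receptor gene Tek 9.57, 13.2 and 4.73 CPM. Clec14a (6.68, 10.8 and 2.04 CPM) and Sox7 (7.12, 9.71 and 3.85 CPM) had the same order. The estimated inter-gene correlation of the list was 1, far above the preset 0.01. Camera called the list as lower (adjusted p = 0.0449), with an estimated correlation it was not called (adjusted p = 0.855), and without cKO 2 the median reverses to 0.26. The microglia and macrophage list had medians of 0.23 and -0.53 (adjusted p = 0.156), led by the border macrophage genes Mrc1 (log2 folds 0.89 and -3.92) and F13a1 (0.71 and -4.85).

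Angiogenic and neurovascular signalling genes had medians of 0.09 and -0.26 over 51 members (camera adjusted p = 0.156), with 3 members higher and 4 lower in both libraries beyond counting error. Rgma, which encodes a repulsive guidance molecule that binds neogenin, had 156 CPM in floxed and 211 ± 0.214 CPM (SD, n = 2) in cKO, with log2 folds of 0.44 and 0.44 and an unadjusted edgeR p of 0.0167 (adjusted p = 1). Igf2 had 374 CPM in floxed, 561 in cKO 1 and 65.1 in cKO 2, and it is also a member of the meninges list. Sparc (0.41 and -0.62) and Igf1 (0.82 and -0.72) went the same way. Igf2 shares 62.8% of its exon bases with Gm49394 on the same strand, so its level is uncertain. Vegfa, chosen after its values were seen, had 67.7 CPM in floxed, 67.6 in cKO 1 and 62.6 in cKO 2.

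**Figure D3:**
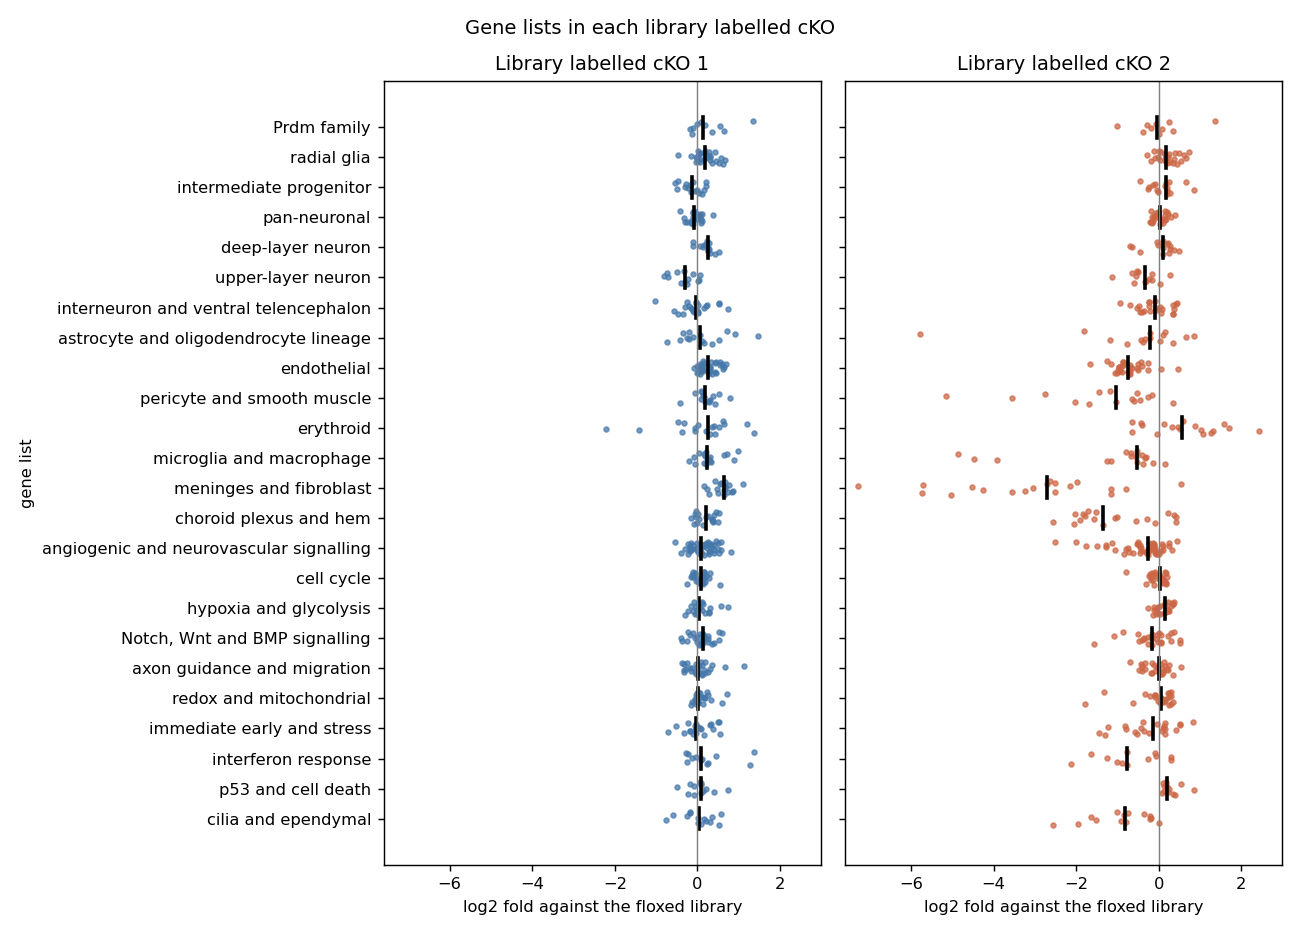
Log2 fold against the floxed library of every tested member of 24 gene lists in cKO 1 (left) and cKO 2 (right). Points are genes and black bars list medians. The meninges and fibroblast median is 0.65 in cKO 1 and -2.72 in cKO 2, while the upper-layer neuron medians are -0.30 and -0.34.

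Of the remaining lists camera called p53 and cell death as higher (medians 0.08 and 0.21, adjusted p = 0.0362) and cilia and ependymal as lower (0.05 and -0.82, adjusted p = 0.0224). Neither was called with an estimated correlation (adjusted p = 0.855 for each). That estimate was 0.231 for the p53 list and 0.714 for the cilia list, above the preset 0.01 behind the calls. In the p53 list Ccng1 (0.41 and 0.22) and Trp53inp1 (0.22 and 0.25) were higher in both, and Bax (-0.22 and 0.34) and Sesn2 (-0.50 and 0.21) were split. In the cilia list Foxj1, the master regulator of motile cilia, had log2 folds of 0.01 and -0.17, and Ccdc40 of -0.24 and -0.20. Erythroid genes had medians of 0.26 and 0.56 (adjusted p = 0.0656), but the alpha-globin gene Hba-a1 had 583 CPM in floxed and 421 and 371 CPM in cKO. Hba-a2 (-0.33 and -0.42) and Hbb-bs (0.01 and -0.39), chosen after their values were seen, are abundant too, and the less abundant Hbb-bt had 81.8 CPM against 127 and 123 CPM. Globin genes have near-identical copies, so these values are uncertain. Haemoglobin genes took 0.157%, 0.126% and 0.172% of counts in cKO 1, cKO 2 and floxed.

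The lists that follow were not called. Hypoxia and glycolysis genes had medians of 0.04 and 0.15 (camera adjusted p = 0.0589), with Egln3 at 0.57 and 0.31. Interneuron and ventral telencephalon genes had medians of -0.04 and -0.08 (0.158), with Lhx6 at -0.57 and -0.36 and Zic1 at 0.75 and 0.37. Redox and mitochondrial genes had medians of 0.02 and 0.07 (0.123), with Hmox1 at 0.59 and -0.61. Axon guidance and migration genes had medians of 0.02 and 0.01 (0.991), with the ubiquitin ligase gene Pdzrn3 at 0.68 and 0.54, the reelin receptor gene Lrp8 at -0.33 and -0.49 and Robo2 at -0.31 and -0.42. Notch, Wnt and BMP signalling genes had medians of 0.13 and -0.16 (0.991), with Smad7 at 0.53 and 0.51 and Tcf7l1 at 0.52 and 0.38. Immediate early and stress genes had medians of -0.02 and -0.14 (0.712), with Arc at -0.72 and -0.57 and Npas4 at -0.53 and -0.81. The interferon response list (0.10 and -0.76, 0.391) and the astrocyte and oligodendrocyte lineage list (0.06 and -0.22, 0.619) included Bst2 at -0.22 and -1.63 and Gja1 at 0.71 and -1.81. The Prdm family had medians of 0.14 and -0.03 (0.362). Gjb6 had 218 counts in cKO 1, 105 in floxed and 0 in cKO 2. Of the 6 symbols in the sex chromosome list, Xist alone was listed in both tables, at 559 CPM in cKO 1, 440 in cKO 2 and 545 in floxed. The table holding cKO 1 listed 1 of these symbols and the table holding cKO 2 listed 2.

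Over the 24 lists, camera with the preset correlation called 8, camera with an estimated correlation 0 and the directional test of fry 0. The mixed test of fry, which takes changes of either direction, fell under the 0.05 threshold for the radial glia list. The estimated-correlation test runs on the 1 residual degree of freedom, so a list that it did not call is not shown to be unaffected. In that test the adjustment gave most lists the same adjusted p, so that value does not rank them. The fitted median and mean had opposite signs in the Prdm family, intermediate progenitor, pan-neuronal, astrocyte and oligodendrocyte, and axon guidance lists, none of them called. With 1 floxed library, a deviation of that library moves both folds alike, and no list test can tell it from genotype.

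Among annotation terms, 0 of 2901 were enriched in the 101 genes higher in both libraries (smallest adjusted p = 0.378, one-sided Fisher exact test) and 0 in the 101 lower in both (1).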

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

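The count of genes called by edgeR's quasi-likelihood test stayed at 0 with DESeq2 size factors, with no expression filter, with at least 1 CPM in every library, without erythroid genes, with limma-voom and with an added 2-fold threshold, and was 1 with total counts and 5 with DESeq2. The number of genes past 2-fold in cKO 1 (589) was 343 with a prior count of 5, 1148 with no filter, 29 at 10 CPM or more, 1819 at 1.5-fold and 121 at 3-fold. That in cKO 2 (1349) was 2136 with no filter, 162 at 10 CPM or more in the higher of the compared libraries, 2842 at 1.5-fold and 490 at 3-fold. Genes past the threshold the same way in both (202) numbered 695 at 1.5-fold, 38 at 3-fold, 13 at 10 CPM or more and 98 with a prior count of 5. The looser and stricter thresholds and filters admit more or fewer genes by construction, and for the gene test the cause was not tested. Leaving out each cKO library gave Prdm16 log2 folds from -0.28 to 0.19, reversing its sign. The called lists numbered 8 with the preset correlation, 0 with an estimated one, which leaves 1 degree of freedom and says nothing of stability, 0 with fry and 9 with total counts, and the 8 were among the 9. Leaving out each cKO library gave medians from -0.74 to 0.26 for the endothelial list, -1.03 to 0.19 for the pericyte and smooth muscle list, -2.72 to 0.65 for the meninges and fibroblast list and -0.82 to 0.051 for the cilia and ependymal list, each of which reversed in sign without cKO 2. The enriched terms among genes higher in both numbered 2 at 1.5-fold, an alternative chosen after seeing the data, and 0 in the planned ones. Of the named genes' alternatives with a test, 161 kept the direction and the side of the threshold, and 6 passed it, which were Ptx3 with total counts and the 5 DESeq2 calls. With a cKO library left out the gene test has no residual degrees of freedom and with the floxed library left out no contrast, so these gave no value. No paired analysis was possible because the columns carry a group but no sample, so the word Blood in 2 of the sample titles could not be matched to a library. The fold of genes with low counts depends on the prior count, as the 98 genes with a prior count of 5 against 202 show.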

Other observations

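Of the tests in this part, the one on diencephalic markers was set before its result was seen, with its interval added later, and the others after.

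Genes lower by over 2-fold in cKO 2 and lower by less than 0.5 on the log2 scale, or higher, in cKO 1, a set chosen after the data were seen, numbered 829 and were enriched for 114 of 2901 annotation terms. They held 54 of the 201 tested genes of the proteinaceous extracellular matrix where 9.83 were expected (adjusted p = 3.53e-22, one-sided Fisher exact test), 19 of 53 of the collagen trimer term (9.02e-10) and 17 of 54 of blood vessel development (1.22e-07). The 101 genes higher by the same rule gave 0 terms. Among meningeal genes, Col1a1 had 89.9 CPM in floxed, 141 in cKO 1 and 2.64 in cKO 2, and Slc6a13, a transporter of the meninges, 25.04, 39.8 and 0.055 CPM, the last on 1 count. Ttr, which encodes the transthyretin of the choroid plexus, had 989, 960 and 302 CPM, and the chemokine gene Cxcl12 had 108, 130 and 26.9 CPM. At 1.5-fold, 2 terms were enriched among 324 genes higher in both libraries, the chloride channel complex (6 of 38 genes, adjusted p = 0.031), with Gabra2, Gabrg1, Gabrr2 and Ano1, and the detection of temperature in pain perception (4 of 12, adjusted p = 0.031), which counts Prdm12 and its overlapping antisense neighbour Gm13425.

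The low meningeal, mural, endothelial and choroid plexus genes of cKO 2 could come from less of these tissues in that dissection, or from a lower level in cKO embryos in general. The lower level was not shared by both libraries labelled cKO. In cKO 1 the meninges and fibroblast median was 0.6485 on the log2 scale and the endothelial median 0.2601. These medians are part of the pattern itself and set 1 library against the single floxed library. They therefore cannot decide on a lower level, or on fewer endothelial cells, in cKO embryos in general. A smaller share of meninges and choroid plexus in cKO 2 cannot be told apart from lower expression in that library: 89.47% of the meninges list lay below a log2 fold of -1, with Zic4 (0.54) and Col5a1 (-0.79) as the exceptions, which restates the pattern and decides neither. Whether the vessel genes of cKO 2 went with the meninges or followed the genotype there also stays open. So does any part of the unexplained word Blood in 1 sample title per group, since no library could be matched to it.

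Higher radial glia and lower upper-layer genes in both libraries labelled cKO may reflect the genotype, the tissue or the floxed library. A smaller share of non-neural tissue in cKO 2 would not reach cKO 1, where the radial glia median was 0.1746 and meningeal genes were higher. The cKO 1 value is part of the pattern itself, so it is no separate test. In cKO 2 the radial glia median was 0.19 and the meninges median -2.72, and a part played by tissue share there stays open. A deviation of the single floxed library cannot be told apart from genotype, because that library enters both folds, and the adjusted p of 0.855 with an estimated correlation, on 1 residual degree of freedom, decides nothing. An effect of the Prdm16 deletion stays open as a hypothesis, untested here, and the Prdm16 count itself was higher in cKO 1.

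Several regional transcription factor genes, chosen after their values were seen, were higher in both libraries labelled cKO, with Prdm12 at 4.30 and 4.35 CPM against 1.61 CPM. Dbx1 had 34 and 20 counts against 0, with lower limits of the count ratio (exact 95% interval) of 7.93 and 4.88, and Bsx 18 and 16 against 0, with lower limits of 3.996 and 3.81. More diencephalic tissue in both dissections could bring such genes. This explanation was to need at least 67% of the tested diencephalic markers higher in both libraries, and to be set aside under 50%. Of 22 markers 12 were tested, and 33.33% (4 of 12) were higher in both, which met the rule as set for setting it aside. The exact 95% interval, added later, ran from 9.93% to 65.1%, below 67% but holding 50%. On that interval the explanation cannot be told apart from other origins. In cKO 1, 6 of 12 were higher and in cKO 2, 8 of 12, with 2 lower in both, and Lhx1 (0.57 and 0.69) and Lhx9 (0.30 and 0.48) were higher in both, while Otp (-1.08 and 0.14) and Fezf1 (-0.96 and 0.31) were split. All 12 had counts in the floxed library too, the most abundant being Dlk1 (33.4, 22.8 and 28.3 CPM in cKO 1, cKO 2 and floxed) and Calb2 (22.6, 32.1 and 21.8 CPM).

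The processed pseudogenes Rps3a2 (1.16, 91.2 and 86.9 CPM) and Rps3a3 (0.152, 86.1 and 77.4 CPM in cKO 1, cKO 2 and floxed) were nearly absent from cKO 1 alone, and with Rps3a1 their sum was 793, 695 and 619 CPM. Myo7a had 4.15, 33.2 and 23.3 CPM, and Dynlt1b 35.5, 75.5 and 113 CPM. The genes of this paragraph were chosen after their values were seen.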
